A study of Arabidopsis thaliana with 6 samples.

How the data were processed

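RNA from rosette leaves of WT and atrap plants, 3 weeks old, was hybridised to Affymetrix arrays, with 3 arrays per genotype. Plants grew at 23 °C with 12 h of light and 12 h of darkness and received no treatment, and RNA was extracted with TRIzol, per the labels' protocols. The deposited values are log2 expression values per probe set made with RMA, per the submitters' processing notes. The software, its version and the probe set definition are not given in the sources used here. The log2 scale was read from the values, which run from 3.12 to 15.01. RMA corrects background, equalises the distributions of the arrays and summarises probes, so a change of all transcripts together would be removed, and changes of dim probe sets are compressed.

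Groups and replicate numbers came from the sample titles. The choice of test, samples, alternatives, gene lists and the rule for named genes was made before the data were examined, except where stated. All 64 control probe sets were left out and 22746 were tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided, Benjamini-Hochberg adjustment). Neither a filter on dim probe sets nor a further normalization was applied. The gene table given with the array paired 13513 probe sets with 1 gene, 503 with several and 8730 with none listed. Names were updated by gene identifier through a gene table of assembly TAIR10.1, which matched 13436 of the 13513. That table was used for names, organelle membership and gene order. The synonym ATRAP in it led to RAP.

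Named genes were RAP and its neighbours, then the 12 highest and 12 lowest log2 fold changes among probe sets of 1 gene past an adjusted p of 0.05 whose groups did not overlap. From each gene list, up to 4 members past the threshold with the largest change were named, or up to 2 with the smallest p where none passed. The results print a selection of these list members. NAI1, NAI2 and JAL23, AT4G11290 of a root-abundant list, control probe sets and the genes singled out for atrap replicate 2 fall outside this rule and were chosen after their values were seen. For a gene with several probe sets, the brightest was used in lists.

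Of 407 locus entries on the 28 planned lists, 56 were measured, and 5 of the lists had at least 5 measured members. A further 33 lists were therefore written after annotation coverage and correlations between arrays had been seen and before any fold change was. They were matched by symbol, so that 1 starch symbol took a pair of genes. Plastid-encoded genes were taken by chromosome, and mitochondrial genes that lacked a locus by symbol. Lists were tested with camera at a preset correlation of 0.01, adjusted within planned and within added lists, and again with an estimated correlation and with fry.

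The scripts were tested on simulated data with the means and spreads of the 22746 probe sets, of which 200 were changed. In the simulated comparison of atrap against WT, 28.8% of changes of 0.5 log2 units were recovered, 79.1% of changes of 1 and 96.1% of changes of 2, and 3.76% of calls were false. A list shifted by 1 log2 unit was found in 10 of 10 simulations. The simulated probe sets varied independently of each other, so these results do not cover genes that vary together.

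Alternatives were a replicate block, a further quantile normalization, median centring, filters at the 30th percentile and at log2 6, an intensity trend, robust variance, array weights, an unmoderated test, stricter thresholds and leaving out each array. Summaries and permutation tests used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and statsmodels 0.14.6, and figures matplotlib 3.10.9.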

Results

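Transcript levels were measured on Affymetrix arrays in rosette leaves of Arabidopsis thaliana, a small flowering plant used as a model species. The leaves came from plants 3 weeks old, either wild type (WT) or carrying the mutation named atrap. Each genotype had 3 arrays, which the labels call biological replicates. The table held 22810 probe sets, of which 64 were manufacturer's controls, so that 22746 were compared. Values ranged from 3.12 to 15.01 on the log2 scale, and array medians lay between 6.50 and 6.57. Arrays have no read depth, and their number limits the precision. The manufacturer's poly-A spike-in controls read 6.90 ± 0.16 in WT and 6.51 ± 0.08 in atrap (mean over 24 probe sets, SD, n = 3 each), with every mutant array below every WT array (exact permutation p = 0.1, two-sided, the smallest that 3 against 3 allows). Of the 64 control probe sets, 29 lay lower in every mutant array than in any WT array and 0 higher. The actin 3-prime minus 5-prime difference, a sign of RNA integrity and labelling, was 2.65 ± 0.04 in WT and 2.29 ± 0.01 in atrap (log2, SD, n = 3 each, exact permutation p = 0.1). A second actin pair differed by -0.15 and a ubiquitin pair by 0.12 between atrap and WT (exact permutation p = 0.1 each), while GAPDH differed by -0.02 (exact permutation p = 0.6). The first WT array read 9.95 for hybridisation spike-ins and the other 5 arrays 10.38 to 10.62.

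The single comparison the labels describe asks which transcripts differ between atrap and WT leaves. The gene table lists ATRAP as a synonym of RAP (AT2G31890), and the labels give no locus for the mutation. The RAP transcript was lower in all 3 mutant arrays. Its level was 7.69 ± 0.22 in WT and 6.53 ± 0.19 in atrap (log2, SD, n = 3 each), a log2 fold change of -1.16 with a standard error of 0.14 (limma, adjusted p = 0.00741). The 3 WT arrays read 7.87, 7.44 and 7.76 and the mutant arrays 6.73, 6.35 and 6.51. Where the mutation lies relative to the probes is not given in the sources used here, so this value checks the labels only as far as the mutation lowers the transcript. The neighbours AT2G31880 and AT2G31900 had no probe set paired with 1 gene here.

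The strongest rise among named genes was that of QQS, an orphan gene linked to starch content, at 2.85 ± 0.24 (log2 fold change ± standard error, n = 3 per group), or 7.23-fold. PYK10, a beta-glucosidase of ER bodies, rose by 2.77 ± 0.24, or 6.80-fold. ER bodies are compartments of the endoplasmic reticulum that store such enzymes, and jacalin-related lectins (JAL) bind them in cell extracts. The lectin genes JAL33 and JAL22 rose by 2.51 ± 0.24 and 1.82 ± 0.24. SMZ, a repressor of flowering of the AP2 family, rose by 1.94 ± 0.30. AT4G15680, AT4G15690 and AT4G15700 rose by 2.36, 1.94 and 1.77, and these neighbouring loci are paralogs. Their probe set names carry no mark of shared probes, and cross-hybridisation was not tested. The remaining genes of the 12 with the highest rise were AT3G14395, AT2G05540, AT1G09500 and AT1G66760, at 2.50, 2.29, 2.13 and 1.96. Adjusted p over these 12 genes ran from 0.0035 for AT1G66760 to 0.0454 for AT4G15700.

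The strongest falls were those of AT1G68600 at -2.85 ± 0.42 and AT5G22460 at -2.85 ± 0.24. AT5G05200 fell by 2.77 on the log2 scale, or 6.84-fold, with a standard error of 0.14 and the smallest adjusted p among the named genes (0.00129). WRKY53, a transcription factor of leaf senescence and defence, fell by 2.54 on the log2 scale with a standard error of 0.54. AT1G64360, AT1G19020, AT4G19430, AT5G59670 and AT3G04210 had log2 fold changes of -2.66, -2.56, -2.38, -2.17 and -2.09. AT4G14020, AT5G35735 and AT3G19550 completed the 12 lowest, at -2.05, -2.04 and -1.97. Some of these genes varied widely among WT plants: the standard deviation of WRKY53 was 1.23 in WT and 0.19 in the mutant. Among the 245 probe sets lower by 2-fold or more, the first WT replicate was the lowest WT array in 85.7%, where 33.3% would fall to each array without preference. Among the 154 higher by 2-fold or more, it was the highest WT array in 72.1%. WT replicate 3 lay over 1 log2 unit above the mean of the other WT arrays in 191 probe sets whose other WT values were within 0.5 of each other, and below in 6. WRKY53 read 8.69 in that array and 6.23 and 7.54 in the others. CML38, the 1 measured gene of the touch, wound and handling list, read 7.58 there and 4.97 and 5.16 in the other WT arrays. Mutant arrays read 4.40 to 4.69 for CML38, and it did not pass (limma, adjusted p = 0.204).

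**Figure D1:**
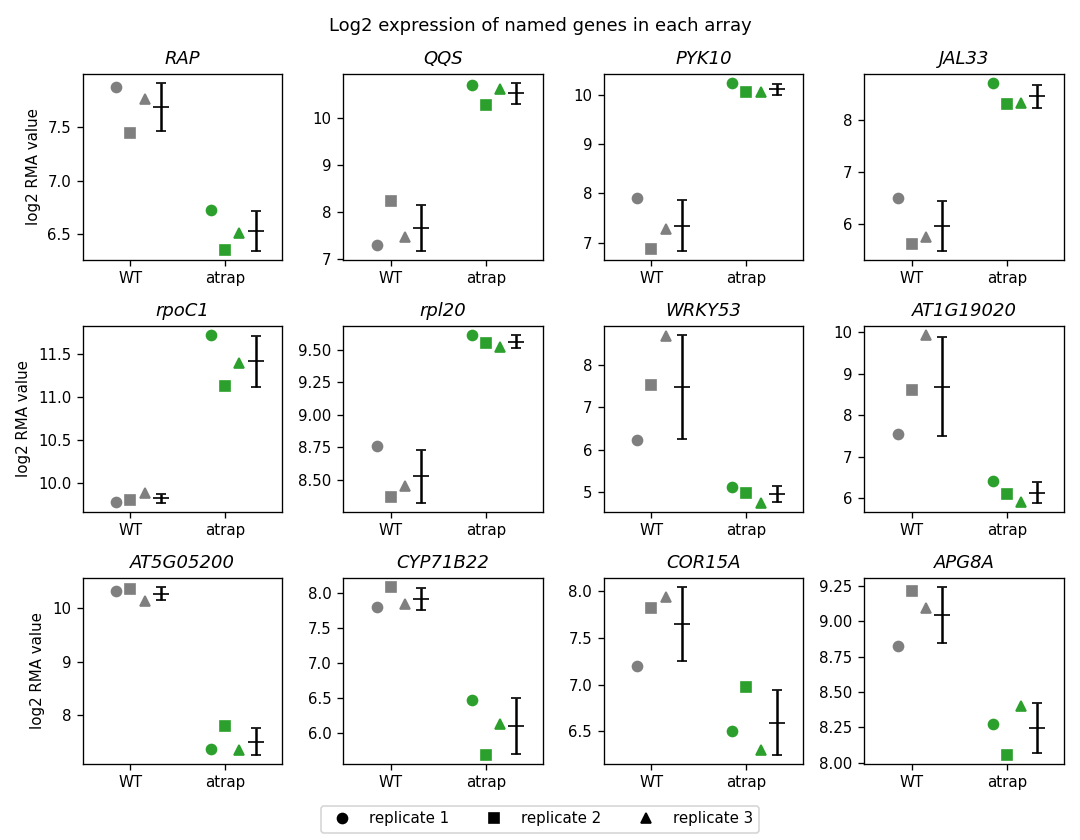
Log2 RMA value (vertical axis) of 12 named genes in each WT (grey) and atrap (green) array. Point shapes mark the replicate number, and the black mark and bar give the group mean and SD (n = 3). RAP lies at 7.69 in WT and 6.53 in atrap, and WRKY53 spreads over an SD of 1.23 among WT arrays.

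Across all probe sets, 2981 passed an adjusted p of 0.05 (13.1% of those tested), 1524 higher and 1457 lower in atrap. A change of at least 1 log2 unit was reached by 399 of them, 154 higher and 245 lower. Centring each array on its median gave 3203 calls with 61.8% higher, against 51.1% higher in the values as deposited. The groups did not overlap for 35.6% of probe sets, where chance gives 10%. The count fell to 438 without WT replicate 2, 1260 without WT replicate 3, 350 without atrap replicate 1 and 629 without atrap replicate 3. With atrap replicate 2 and 1 WT array both left out, alternatives chosen after seeing the data, it was 4483 without WT replicate 1 and 2153 without WT replicate 3. It was 48 with a test that does not share variance between probe sets.

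Genes encoded in the plastid genome shifted upward as a list. Of 69 measured, 21 rose and 1 fell, or 22 and 3 when adjusted over the list alone (camera, adjusted p = 0.00263). The shift was not past the threshold with an estimated correlation (adjusted p = 0.253 with an estimated correlation). The rises were those of rpoC1 at 1.59 ± 0.15, rpoC2 at 1.39 ± 0.10, ndhD at 1.16 ± 0.11 and ycf3 at 1.13 ± 0.10 among others. The genes rpoC1 and rpoC2 encode subunits of the plastid RNA polymerase, ndhD a subunit of the NDH complex, and ycf3 a photosystem I assembly factor. The gene that fell was ndhJ, by 0.36 on the log2 scale.

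The plastid genes were then divided by function, in lists added once annotation coverage was known. The polymerase and housekeeping group rose in 6 of 7 genes, among them clpP (protease subunit) at 0.62 ± 0.08 and accD (fatty acid synthesis) at 0.55 ± 0.09 (camera, adjusted p = 6.37e-06). With an estimated correlation its adjusted p = 0.223. The gene of this group that did not pass was rpoB, a further polymerase gene, with a log2 change of 0.16 (limma, adjusted p = 0.492). Its WT level was 4.71, where changes are compressed, so this does not show an unchanged level. Plastid-encoded ribosomal protein genes rose in 10 of 15, with rpl20 at 1.04, rps16 at 0.99, rps2 at 0.83 and rps15 at 0.82 (camera, adjusted p = 4.04e-06, and adjusted p = 0.396 with an estimated correlation). Of 20 photosystem subunit genes, psaC rose by 0.82 ± 0.15 and 19 did not pass. The largest negative changes were -0.82 for psbK and -0.66 for psbI (limma, adjusted p = 0.0702 and 0.112). The change was positive in 6 of the 20. The median of that list was -0.11 and its camera adjusted p was 0.110. The list of ATP synthase, cytochrome b6f and Rubisco genes had rbcL at 0.55 ± 0.10 as its single call of 13 (camera, adjusted p = 0.612). The NDH subunits had 2 genes higher (ndhD, ndhH) and 1 lower (ndhJ) of 10, with a camera adjusted p of 0.420. Of 16 mitochondrion-encoded genes, 0 passed by limma, or 0 when adjusted over the list alone. Their WT levels ran from 4.37 for nad6 to 9.69 for ccb382 (log2 means, n = 3). Most lay under log2 6, where changes are compressed, so the absence of calls does not show unchanged levels. The smallest unadjusted p values in this list were 0.0104 for nad1 and 0.0166 for nad9. The nad1 value is that of its brightest probe set, at a log2 change of -0.29, and its others ran from -0.22 to 0.21, so they disagree in direction.

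**Figure D2:**
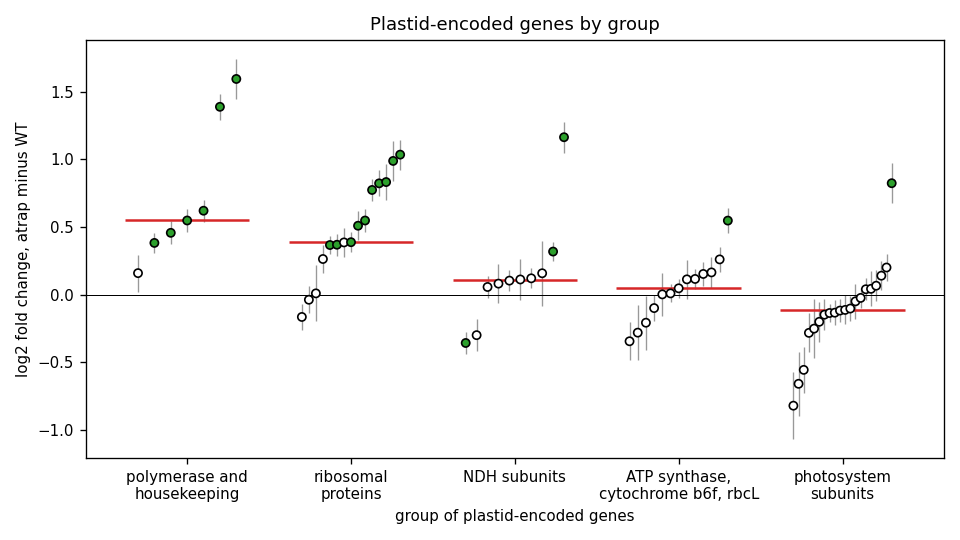
Log2 fold change, atrap minus WT (vertical axis), of plastid-encoded genes in 5 functional groups (horizontal axis). Each point is 1 gene with its standard error, green when past an adjusted p of 0.05, and the red line is the group's median. The median is 0.55 for polymerase and housekeeping genes and -0.11 for photosystem subunits.

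Nuclear genes for plastid ribosomal proteins shifted upward too, with 3 of 8 past the threshold and 8 of 8 when adjusted over the list alone (camera, adjusted p = 0.000174). The adjusted p = 0.253 with an estimated correlation. The 3 genes were AT4G17560 at 0.71 ± 0.12, AT5G47190 at 0.50 ± 0.10 and AT5G65220 at 0.39 ± 0.07. RH39, a helicase of plastid ribosomal RNA maturation, rose by 0.77 ± 0.13, as 1 of 2 members of its list (2 when adjusted over the list alone). Of 14 genes of tetrapyrrole synthesis, the pathway to chlorophyll and heme, 6 rose (camera, adjusted p = 0.00785, and adjusted p = 0.457 with an estimated correlation), with GSA1 at 0.66, HEME2 at 0.60, HEME1 at 0.53 and CHLI2 at 0.53. PORB, a protochlorophyllide oxidoreductase of that list, had a log2 change of -0.61 and an adjusted p of 0.0694, and 7 members were higher and 1 lower when adjusted over the list alone. Of 15 genes on a list headed organelle RNA editing and splicing, 5 rose (camera, adjusted p = 0.000137, and adjusted p = 0.329 with an estimated correlation), with OTP81 at 0.71, PPR336 at 0.59, CFM3B at 0.50 and CFM3A at 0.45. PPR336 was placed on it by symbol, and whether it acts in editing or splicing was not checked. For photosystem antenna and electron transport genes of the nucleus, LHCB4.3 fell by 0.77 on the log2 scale, as 1 of 8 (1 when adjusted over the list alone), and the list had a camera adjusted p of 0.0534. In the Calvin-Benson cycle, 0 of 3 passed by limma (0 when adjusted over the list alone), with RCA at a log2 change of -0.0045 and an unadjusted p of 0.950. These 3 genes read 13.50 to 14.91 in WT (log2 means, n = 3), near the highest value of 15.01. Compression of bright probe sets was not tested for them.

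The ER-body list rose in 5 of 7 genes and fell in 1 (camera, adjusted p = 0.000137, and adjusted p = 0.329 with an estimated correlation). Beside PYK10, JAL33 and JAL22, JAL34 rose by 1.69 ± 0.13 and NAI2 by 1.57 ± 0.17, while JAL23 fell by 1.39 on the log2 scale. NAI1, a transcription factor needed for ER bodies, had a log2 change of 0.30 and an adjusted p of 0.212. Root markers EXPA7 and EXPA18 had log2 changes of 0.24 and -0.05, with 0 of 2 past the threshold by limma (1 when adjusted over the list alone).

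The 6 WRKY transcription factors matched by symbol shifted downward as a list (camera, adjusted p = 0.0109, and adjusted p = 0.253 with an estimated correlation). WRKY53 and WRKY47 were lower, 2 of 6 (2 when adjusted over the list alone). The mean log2 change was -0.66, with WRKY53 at -2.54, and the median was -0.42. Family members without a listed gene name were not covered. Of 10 autophagy genes, mostly of the ATG8 family that marks autophagosome membranes, 5 fell (camera, adjusted p = 3.46e-06, and adjusted p = 0.396 with an estimated correlation). APG8A fell by 0.80 on the log2 scale, ATG8H by 0.69, APG8H by 0.63 and ATG8B by 0.62. Atrap replicate 2 was the lowest mutant array for all 10 genes, and ATG8E had a log2 change of -0.87 with it and -0.18 without it. The median of the list was -0.62 with that array and -0.51 without it, and 3 genes then passed (camera, adjusted p = 2.39e-05). Without atrap replicate 1 or 3, 0 and 2 genes passed by limma. Of 14 dehydration and cold genes, COR15A fell by 1.06, XERICO by 0.79 and LEA4-5 by 0.63 on the log2 scale (camera, adjusted p = 0.0231, and adjusted p = 0.396 with an estimated correlation). Of 9 starch genes, APL3, a subunit of ADP-glucose pyrophosphorylase, fell by 1.28 on the log2 scale, and APL4 and 1 of the genes with the symbol PWD fell by 0.31 and 0.64 (camera, adjusted p = 0.00559, and adjusted p = 0.329 with an estimated correlation). NDB2, an alternative NADH dehydrogenase, fell by 1.12 on the log2 scale, as 1 of 2 members of its list (1 lower and 1 higher when adjusted over the list alone). The markers of guard cells had 0 of 3 past the threshold by limma (0 when adjusted over the list alone), and TRY, which acts in trichome patterning, fell by 0.45 on the log2 scale.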

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

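The alternatives that leave out a pair of arrays were chosen after seeing the data. The count of 2981 probe sets stayed within 1.5 times under quantile normalization, median centring, both dim filters, the intensity trend and robust variance (2886 to 3203). It was 5325 with array weights, 48 with the unmoderated test, 399 with a log2 change of at least 1, 350 at an adjusted p of 0.01, 1541 over probe sets of 1 gene and 4483 without WT replicate 1 and atrap replicate 2, and 2153 without WT replicate 3 and atrap replicate 2. The drop at stricter thresholds and over fewer probe sets follows from their construction, and for the others the cause was not tested. Leaving out 1 array gave 350 to 3863 calls, with 438 without WT replicate 2, 1260 without WT replicate 3, 350 without atrap replicate 1 and 629 without atrap replicate 3. Planned lists past the threshold numbered 3, with 3 to 4 when 1 array was left out, 4 with fry and 0 with an estimated correlation. Added lists numbered 12, with 9 to 14 when 1 array was left out, 6 with fry and 0 with an estimated correlation. The set test was not run under robust variance. Of 115 named probe sets past the threshold, 113 lost it under at least 1 alternative. All 113 did so with the unmoderated test, 78 without WT replicate 2 and 77 without atrap replicate 1. Without atrap replicate 3 it was 67, and without WT replicate 3 it was 41. Of the 115, 0 reversed direction by limma or the unmoderated test. The named probe sets not past the threshold are left out of that count.

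The replicate block gave 2101 calls, of which 1931 were shared with the 2981. The main fit did not use the replicate numbers as a block, a choice made before the data were examined. Deviations of same-numbered arrays correlated at 0.13, 0.02 and -0.15, which gave no clear sign that the numbers pair the plants.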

Other observations

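Of the tests here, those of root RNA, WT spread, a shared plastid factor, admixed mutant RNA, the WT axis and the splits were chosen after the values they bear on had been seen, in whole or part. Genes of other lists passed the threshold too, and only a selection of them is given here. EXPA16, an expansin that loosens cell walls, fell by 1.73 on the log2 scale, with EXLB1 and EXPB1 at -1.11 and -1.08 and EXPA15 at 0.63, and the expansin list of 18 had a camera adjusted p of 0.0683. GH9B8, a cellulase, fell by 1.39 on the log2 scale, as 1 of 15 (camera, adjusted p = 0.0954). SWEET2 and SWEET16, sugar transporters, rose by 1.25 and 0.74 while SWEET4 fell by 0.82, 3 calls among 14 genes (camera, adjusted p = 0.414). TBL37 rose from 8.69 to 9.69 (log2 means, n = 3 each) and TBL38 fell by 1.22 on the log2 scale, in a list of 22 (camera, adjusted p = 0.244). The XTH list had 0 of 9 past the threshold by limma (camera, adjusted p = 0.612). MSRB6 rose by 1.23 while its paralog MSRB5 fell by 1.16, both methionine sulfoxide reductases. The list they were placed on, headed plastid redox, had 4 higher and 1 lower of 14 (camera, adjusted p = 0.275). Whether the 2 proteins act in plastids was not checked. THI2.2, a thionin, rose by 1.57 ± 0.10. Its list of 20 defence genes had 1 higher and 2 lower, WRKY53 and PUB24 (camera, adjusted p = 0.413).

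The CYP71B cytochromes P450 had 4 lower of 19 (camera, adjusted p = 0.0231, and adjusted p = 0.396 with an estimated correlation), led by CYP71B22 at -1.81, CYP71B23 at -1.80 and CYP71B24 at -1.39, paralogs for which cross-hybridisation was not tested. The IQD list had 4 lower of 15 (adjusted p = 0.0394, and 0.415 with an estimated correlation) and the bZIP list 1 of 14 (adjusted p = 0.0231, and 0.415 with an estimated correlation). In the cell division and chromatin list, HTB1 and ASF1B rose by 0.63 and 0.48, 2 of 19 (adjusted p = 0.0292, and 0.590 with an estimated correlation).

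Plastid-encoded genes moved apart by function. A yield or labelling factor of the same size for all plastid RNA would move the groups alike. Instead, the polymerase and housekeeping median exceeded the photosystem median by 0.66 (permutation p = 0.00486 over 7 and 20 genes, which are not independent replicates). A labelling effect that differs between plastid transcripts could part the groups and was not tested. Compression of bright probe sets would close the gap among dimmer genes, yet below log2 11 it was 1.09 (permutation p = 0.0300 over 4 and 10 genes, two-sided). Across the 4 such tests Benjamini-Hochberg adjusted values were at most 0.0300. No biological explanation was tested. A technical difference between groups stays open, since poly-A spike-in controls differed by -0.38 log2 units between atrap and WT (exact permutation p = 0.1, the smallest 3 against 3 allows) and the actin 3-prime minus 5-prime difference by -0.35 (exact permutation p = 0.1).

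In the ER-body list 5 of 7 genes rose, JAL23 fell and NAI1 did not pass, and the list's adjusted p = 0.329 with an estimated correlation. Over all 7 genes the median gap between the lowest mutant and the highest WT array was 1.21. Most of these genes had already been called higher, and all called probe sets lacked overlap between groups, so a positive gap was given in advance. The gap therefore cannot decide whether spread among WT plants plays a part. Root tissue in the mutant samples could raise PYK10, which is abundant in roots. A list of 18 root-abundant genes, 2 of which had been seen, had 7 measured, with a median log2 change of 0.13, 1 past the threshold (AT4G11290 at 0.61) and levels near the floor, so root RNA stays open.

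Genes changed in atrap varied among WT arrays, with WT replicate 1 nearest the mutant. Over all probe sets, that array correlated with atrap replicates 1, 2 and 3 at 0.9915, 0.9875 and 0.9910. It correlated with WT replicates 2 and 3 at 0.9946 and 0.9895. WT replicate 3 was the highest WT array in 66.9% of the 245 probe sets lower by 2-fold or more, against 33.3% without preference. Admixed mutant RNA in WT replicate 1 would lower RAP there, but RAP lay at a fraction of -0.25 of the way toward the mutant, where the 245 probe sets lower by 2-fold had a median fraction of 0.41 and the 154 higher by 2-fold 0.29. A differing state of the WT plants may contribute: across probe sets, WT replicate 3 minus 1 correlated with the mutant mean minus WT replicate 2 at -0.50. The other arrangements without shared arrays gave -0.51 (WT 2 minus 1) and -0.10 (WT 3 minus 2), so this correlation rests mainly on WT replicate 1. Hybridisation spike-ins also read lower in that array, 9.95 against 10.59 and 10.62 in the other WT arrays, so a technical source stays open.

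A chromosome segment around RAP that differs between the lines was tested on the 51 measured genes centred on it. Of the 50 neighbours 12 were called, against a median of 6, and 1.7% of all 12967 overlapping windows held as many beside their central gene. With RAP itself, which was known to be called, the count was 13, 7 higher and 6 lower. This is consistent with a linked segment as a hypothesis, though changes in both directions and overlap between windows limit it.

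Splits of the 6 arrays number 10, too few for a share under 0.05. The real split, 1 of 10, gave 2981 probe sets against 0 in the highest other (limma), 3 planned lists against 2, and 12 added lists against 7. Each other split has both genotypes on both sides, so a genotype difference widens its spread within sides and lowers its calls. The other splits are therefore no measure of what arrays without a difference would give. At an unadjusted p of 0.05 by limma, the real split gave 6726 probe sets and the others up to 1957.

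In atrap replicate 2, GI, a clock gene, read 7.40 against 5.47 and 5.37 in the other mutant arrays, and ATG8E read 5.67 against 7.62 and 7.81. That array lay over 1 log2 unit above the mean of the other mutant arrays in 158 probe sets and below in 108, counted where those were within 0.5 of each other. By the same count WT replicate 3 lay above in 191 and below in 6, and WT replicate 1 above in 3 and below in 42.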
